A study of Homo sapiens with 10 samples.

How the data were processed

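RNA from HCT116 cells was measured on 10 one-colour Agilent expression arrays, 5 of Bevacizumab-adapted and 5 of parental cells, with 43118 non-control spots and 34127 probes each, 999 of them in 10 copies. Per the file headers the authors' scans were read with Agilent Feature Extraction 9.5.3.1, given as 9.5 in the labels. Per the file headers the processed signal is an intensity in arbitrary fluorescence units, background-subtracted and detrended within the array, with a surrogate value for spots at background and no normalization between arrays. The mean spot and median local background signals are also intensity values per the file headers, without correction. Flags of 0 or 1 per the file headers give whether a spot was well above background, saturated or an outlier. The authors' deposited table holds a rank product score, a fold change headed log2, a p-value and an estimated share of false positives for selected probes. The direction of the fold change, its base beyond that header, the threshold and the steps before it are not stated in the authors' deposited files. In 15 of its fold changes the decimal sign was lost and was restored from the digits.

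Spots with an outlier flag were left out (4919 over the 10 arrays), copies of a probe were averaged, and log2 of the processed signal was shifted by the array's 75th percentile. Genes were kept where a probe was well above background on all arrays of at least 1 group, and each symbol was represented by its brightest probe. Symbols were updated from a RefSeq table on GRCh38.p14 by accession for 24827 probes, by symbol for 1276 and by synonym for 500, and the name on the array was kept for 7524. Probe coordinates are those of hg18 in the files, for which no exon annotation was at hand. Adapted arrays were compared with parental arrays by limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 36 gene lists were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, for lists with at least 5 measured genes. A measured list gene is one kept by the filter on dim probes above. A list gene not measured may thus be dim or lack a probe. The files were read with the R packages jsonlite 2.0.0 and data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9.

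The groups, this comparison, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The scan session as a block, the replicate block, the omission of saturated probes and every alternative to the fit with the block were chosen after seeing the data. So was the omission of parental 5 from that fit, which rested on its low signal and its low correlation with the other arrays. Leaving out each array in turn, parental 5 included, was planned for the fit over 10 arrays. Named genes were (a) the 10 with the largest rise and the 10 with the largest fall among those past the threshold, well above background and unsaturated on all arrays of the fit, without overlap between groups, with a gene symbol and with the same direction on the slide that holds both groups. They were also (b) up to 5 per direction detected on all 5 arrays of a group and on none of the other, and (c) all measured VEGF list members and, in each other list, up to 4 members past the threshold and 2 others with the largest difference. Genes named outside this rule are said to be so. Where no parental array was well above background, the fold is a lower bound. Genes saturated in both groups get no fold. The number of arrays limits the precision of every value.

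The code was tested on simulated data with each gene's residual spread on these arrays. Over 5 against 5 arrays it recovered 0 of 66 genes changed by 0.5 on the log2 scale, 19 of 67 changed by 1 and 54 of 67 changed by 2, and called 3 of 17912 unchanged genes. With the block and 5 against 4 arrays it recovered 8 of 66, 48 of 67 and 66 of 67, and called 1 of 18011 unchanged genes. A list shifted by 0.5 was recovered by all 3 set tests in both, and with the block camera also called 1 of the 34 other lists. The simulated noise was independent between genes. It therefore could not show how the set tests behave under the correlation between genes of a real list. Each gene had the same spread on all simulated arrays, so parental 5 did not stand apart. The 5 against 5 run also held no shift between scan sessions. Its recovery and false calls therefore do not cover these features of the real arrays. The alternatives were other background corrections, normalizations, filters, probe summaries, slide and session blocks, variance models, array weights, thresholds and set tests, and the omission of each array. Left out were control spots, and the authors' values as an alternative, since the deposited table holds no value per array.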

Results

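HCT116, an established human colorectal cancer cell line, was profiled after adaptation to Bevacizumab, an antibody that binds the growth factor VEGF-A, and beside it without adaptation. The question stated for the series was how gene expression in the adapted cells compared with that in unadapted cells, here called parental. Total RNA was hybridised to 10 single-channel Agilent arrays, 5 from cells kept at 250 µg/ml Bevacizumab and 5 from cells without it, all in medium with 10% serum. Adaptation and the presence of the antibody therefore cannot be told apart. Nothing in the labels says whether arrays of a group came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision. The 75th percentile of the processed signal was 384 on parental 5 and between 1083 and 2738 on the other arrays. The spots well above background numbered 27516 on parental 5 and 29898 to 34740 on the others, of 43118. Scan session 1 held parental 1 and 2 and adapted 1 and 2 on 1 slide, and session 2 held the other 3 adapted arrays and the other 3 parental arrays on 1 slide each.

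**Figure D1:**
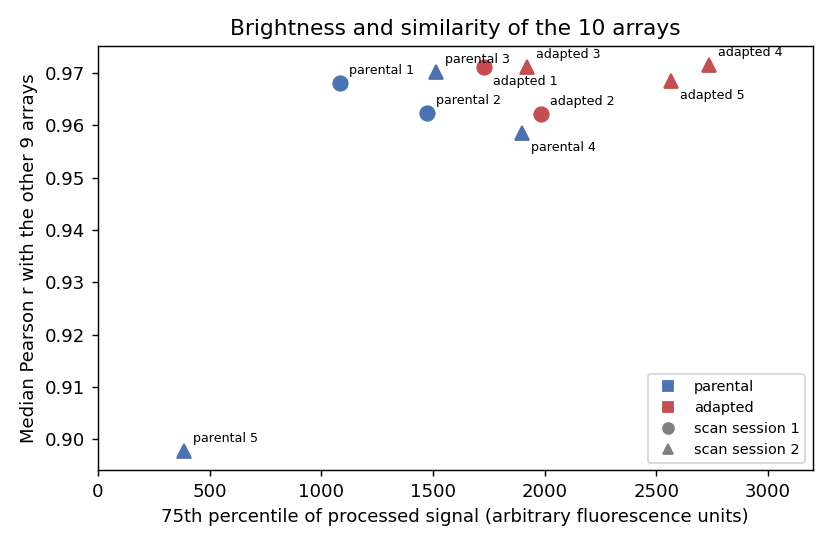
Each point is 1 array, with the 75th percentile of its processed signal on the horizontal axis and its median Pearson correlation with the other 9 arrays on the vertical axis, coloured by group and shaped by scan session. Parental 5 sits apart at 384 and 0.898, while the other arrays lie between 0.959 and 0.971.

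In adapted cells the transcript of IL32, a proinflammatory cytokine, fell by 2.75 on the log2 scale (SE 0.29, limma adjusted p = 0.0109, 5 adapted and 5 parental arrays). PADI1, a peptidylarginine deiminase, fell by 2.44 (SE 0.27, adjusted p = 0.0109), and HKDC1, a hexokinase family member, by 1.5 (SE 0.21, adjusted p = 0.0459). ANXA10, an annexin, rose by 2.03 ± 0.24 (SE, adjusted p = 0.0143), and MSR1, a scavenger receptor, was well above background on all 5 adapted arrays and on none of the 5 parental arrays, at least 2.50-fold higher (adjusted p = 0.0352). The transcripts LOC344887 and ENST00000431042, named here after their values were seen because the list is short, fell by 1.82 and 1.47 (adjusted p = 0.0109 and 0.0459). These 7 genes, 2 higher and 5 lower, were all that passed among 18132 tested with limma over the 10 arrays, and all 7 differed by at least 2-fold. At an unadjusted p under 0.05, 962 genes did. In a limma fit of single probes over the 10 arrays, a probe of ADGRL2 rose by 3.79 (adjusted p = 0.0104). It is named here after its value was seen. The same probe stands at 0.663 in the authors' deposited table, so the size of its rise is uncertain. ADGRL2 was represented by a brighter probe, which was not called. The calls rested on every adapted array: with any single one of the 5 left out, or parental 4, limma called no gene (lowest adjusted p from 0.0544 to 0.0682, with 429 to 1134 genes at an unadjusted p under 0.05), and without parental 5 it called 5 higher and 7 lower.

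With the scan session as a block and parental 5 left out, a fit chosen after seeing the data from among several, 25 genes were higher and 63 lower in adapted cells among 18231 tested, 15 and 24 of them by at least 2-fold. These included the 7 above. Leaving out any single array other than adapted 1 or 2 lowered these counts to 11 to 15 higher and 30 to 42 lower, and they were 24 and 67 without adapted 1 and 19 and 49 without adapted 2. With the block and all 10 arrays, 8 were higher and 14 lower. With the replicate number as a block, the counts were 0 and 2 over 10 arrays and 6 and 7 without parental 5. With normexp background correction, limma called none in either fit, with 601 genes at an unadjusted p under 0.05 over 10 arrays and 1109 with the block, where all 88 genes had the same sign. The values that follow are log2 differences, adapted minus parental, with their standard errors from the fit with the block on 5 adapted and 4 parental arrays, unless another fit is named. Session 2 values leave out parental 5.

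In adapted cells DKK4, a secreted WNT antagonist, and ODAM, an ameloblast-associated secreted protein, were well above background on all 5 adapted arrays and on none of the 5 parental arrays, at least 2.04-fold and 2.36-fold higher (adjusted p = 0.00269 and 0.00134). Over 10 arrays without the block neither passed (adjusted p = 0.245 and 0.568), and ODAM on parental 5, at -5.93, lay within the range of the adapted arrays. ANXA10 rose by 1.82 ± 0.11 (SE, adjusted p = 3.05e-04), with 1.71 in session 1 and 1.91 in session 2. Its normalized log2 signal was -3.53 ± 0.12 on adapted arrays and -5.56 ± 0.49 on parental arrays (SD, n = 5 each). TM4SF1, a tetraspanin-like membrane protein, rose by 1.81 ± 0.15 (SE, adjusted p = 6.03e-04), and CEMIP, a hyaluronan-degrading protein listed on the array as KIAA1199, by 1.59 ± 0.13 (SE, adjusted p = 5.93e-04). ANKRD22, TUBAL3, GASK1B, APOBEC3G, a cytidine deaminase, MEF2C, a transcription factor, BST2, an interferon-induced membrane protein, and KLHL41 rose by 0.95 to 1.36 (adjusted p from 6.54e-04 to 0.0392). GAGE12F, a cancer-testis antigen with near-identical family copies that 1 probe cannot separate, was at least 1.29-fold higher (adjusted p = 0.0363, and 0.785 over 10 arrays without the block). CETN4P was also well above background on all adapted and no parental arrays and did not pass (adjusted p = 0.129).

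Among the transcripts that fell, IL32 fell by 2.65 (SE 0.20, adjusted p = 5.93e-04), with -2.30 in session 1 and -2.94 in session 2, and its other probe had the same sign. Its normalized log2 signal was -5.02 ± 0.34 on adapted arrays and -2.27 ± 0.59 on parental arrays (SD, n = 5 each). TGFBI, an extracellular matrix protein induced by TGF-beta, fell by 2.65 (SE 0.22, adjusted p = 6.28e-04), with -3.31 in session 1 and -2.10 in session 2. Its normalized log2 signal was -5.50 ± 0.49 on adapted arrays and -3.03 ± 1.25 on parental arrays (SD, n = 5 each), and this difference over all 10 arrays without the block, -2.48 ± 0.53 (SE), did not pass (adjusted p = 0.472). PADI1 fell by 2.25, EXO5, an exonuclease, by 1.72, HKDC1 by 1.49, PRF1, which encodes perforin, by 1.44, and DCLK1, a kinase used as a tuft cell marker, by 1.24, with adjusted p from 5.93e-04 to 0.00994. SLC2A3, which encodes the glucose transporter GLUT3, CALB2, a calcium-binding protein, and IL20RB, a cytokine receptor chain, fell by 1.21, 1.20 and 1.16. The probes lay on the hg18 build, for example at chromosome 16, 3059309 to 3059368 for IL32, at chromosome 5, 135427242 to 135427301 for TGFBI, at chromosome 8, 16009837 to 16009896 for MSR1 and at chromosome 8, 42351439 to 42351498 for DKK4.

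**Figure D2:**
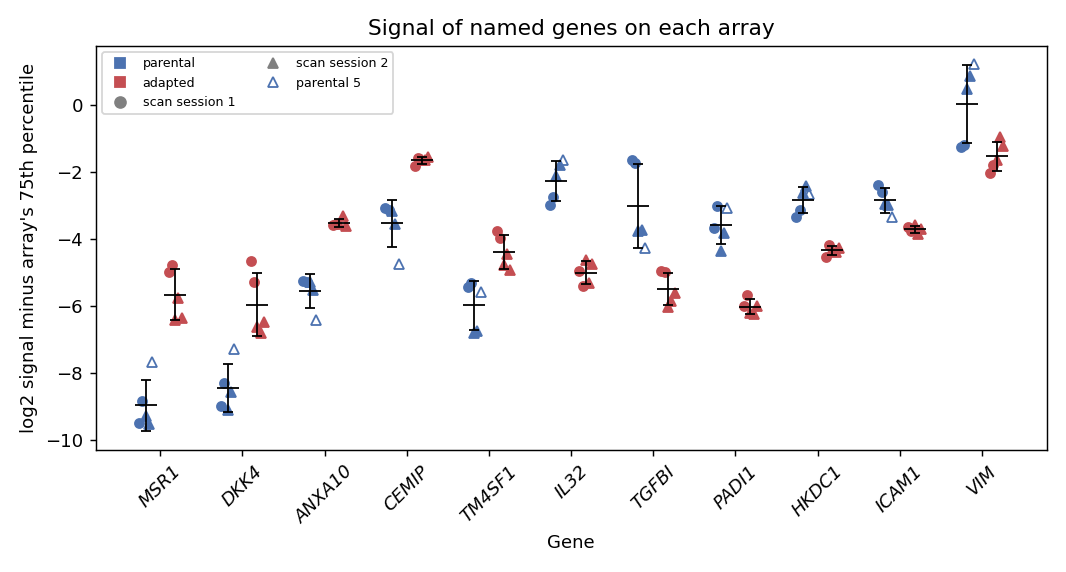
Normalized log2 signal (log2 signal minus the array's 75th percentile) on the vertical axis for 11 genes, 1 symbol per array, coloured by group and shaped by scan session, with parental 5 drawn open and with the mean and SD of each group (n = 5) as a bar. IL32 lies at -5.02 ± 0.34 on adapted and -2.27 ± 0.59 on parental arrays, and MSR1 at -5.67 ± 0.77 and -8.98 ± 0.77, where no parental array was well above background.

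In the list of VEGF ligands and receptors, which includes VEGFA, the gene of the antibody's target, no measured member was called. VEGFC, FLT1, KDR, FLT4 and NRP2 of this list had no probe left after the filter on dim probes, so no difference is given for them. Of 5 measured members, VEGFA differed by -0.45 ± 0.18 (SE, adjusted p = 0.319), VEGFB by 0.09 ± 0.10, VEGFD by -0.24 ± 0.11, PGF by -0.18 ± 0.13 and NRP1 by -0.30 ± 0.16 (0.01 in session 1), and none passed. The list median was -0.24 (camera adjusted p = 0.137). Of 30 other angiogenic ligands none passed over all genes, while 4 were lower adjusted over the list alone. Among these EDN1, endothelin 1, differed by -0.77 ± 0.18 and ANGPT2 by -1.28 ± 0.30 (-2.24 in session 1 and -0.48 in session 2), and the list, with a median of -0.08, was not called by camera (adjusted p = 0.167). The rotation test fry, which does not compare a list with other genes, called it lower (adjusted p = 0.0107, and 0.0419 over 10 arrays without the block). Hypoxia targets had a median of -0.17 over 31 genes and were called lower by camera (adjusted p = 0.00451, and adjusted p = 0.151 with an estimated correlation). In that list SLC2A3 alone fell over all genes, CA9 differed by -0.57 ± 0.27 (0.19 in session 1) and NDRG1 by -0.50 ± 0.18 (-0.09 in session 1 and -0.83 in session 2), and the list medians were -0.09 in session 1 and -0.18 in session 2.

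Mesenchymal genes and regulators of the epithelial-mesenchymal transition were lower as a list, with a median of -0.24 over 20 genes, 18 of them below 0 (camera adjusted p = 3.11e-04, and adjusted p = 0.151 with an estimated correlation). TGFBI passed over all genes and 6 members were lower adjusted over the list alone. VIM, the intermediate filament vimentin, differed by -1.37 ± 0.25 (SE, adjusted p = 0.0520, with -0.68 in session 1 and -1.94 in session 2) and AXL, a receptor kinase, by -0.65 ± 0.16. List medians were -0.10 in session 1 and -0.41 in session 2. Adhesion and integrin genes were also lower, with a median of -0.22 over 25 genes (adjusted p = 5.88e-04, and adjusted p = 0.15 with an estimated correlation). Of these ICAM1, an intercellular adhesion molecule, fell by 0.97 (SE 0.13, adjusted p = 0.00967) and LAMB3, a laminin chain, by 0.76 (SE 0.10, adjusted p = 0.0120). YAP and TEAD targets had a median of -0.20 over 18 genes, -0.28 in session 1 and -0.25 in session 2 (adjusted p = 0.00286, and adjusted p = 0.151 with an estimated correlation), with CCN2 at -0.91 ± 0.20 and F3 at -0.72 ± 0.18 (-1.13 in session 1 and -0.39 in session 2). None passed over all genes and 6 were lower adjusted over the list alone. The TGF-beta target list was not called by camera (median -0.02, adjusted p = 0.429) and ID3 at 0.40 ± 0.12 had the opposite sign to TGFBI and CCN2.

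WNT targets were higher as a list, with a median of 0.10 over 18 genes (camera adjusted p = 0.00451, and adjusted p = 0.15 with an estimated correlation) and medians of 0.17 in session 1 and 0.12 in session 2. DKK4 rose over all genes, AXIN2, a feedback inhibitor of WNT signalling, differed by 0.62 ± 0.13 (SE, adjusted p = 0.0788, with its other probe of the opposite sign) and DKK1, a secreted antagonist, by 0.45 ± 0.12. These 3 were higher adjusted over the list alone. In the stem cell list DCLK1 fell over all genes while the list was not called by camera (median -0.01, adjusted p = 0.973). Cancer-testis antigens were called higher (median 0.13 over 14 genes, adjusted p = 0.00891, and adjusted p = 0.151 with an estimated correlation), with PAGE4 at 0.76 ± 0.14 and MAGEA1 at 0.75 ± 0.15, both higher adjusted over the list alone.

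Cholesterol synthesis genes were higher as a list, with a median of 0.32 over 25 genes, 23 of them above 0 (camera adjusted p = 1.17e-08, and adjusted p = 0.186 with an estimated correlation). MSMO1, a methylsterol oxidase, differed by 0.84 ± 0.16 (SE, adjusted p = 0.0589) and HMGCS1 by 0.65 ± 0.26 (0.01 in session 1 and 1.19 in session 2), no member passed over all genes, and 3 were higher adjusted over the list alone. The shift did not hold within session 1, where both groups shared a slide and the list median was 0.01. It was 0.48 in session 2, where each group had its own slide. Fatty acid synthesis and desaturation genes had a median of 0.15 over 23 genes (adjusted p = 0.0117, and adjusted p = 0.282 with an estimated correlation), with -0.01 in session 1 and 0.22 in session 2. Genes of the integrated stress response and amino acid metabolism were lower, with a median of -0.26 over 30 genes, 27 of them below 0 (adjusted p = 8.42e-06, and adjusted p = 0.15 with an estimated correlation). The medians of this list were -0.28 in session 1 and -0.20 in session 2, no member passed alone, and CBS differed by -0.54 ± 0.20 (0.00 in session 1 and -0.98 in session 2). Targets of NRF2 and xenobiotic metabolism genes had a median of -0.19 over 33 genes (adjusted p = 2.56e-04, and adjusted p = 0.15 with an estimated correlation), -0.15 in session 1 and -0.17 in session 2, with the aldo-keto reductase AKR1C3 at -0.91 ± 0.21 (-1.52 in session 1 and -0.40 in session 2).

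Ribosomal protein, glycolysis, histone and respiratory chain genes (median -0.10) had lower normalized signals in adapted cells. The respiratory chain was not lower with quantile normalization (0.02, adjusted p = 0.322), and over 10 arrays without saturated probes its median was 0.08 and that of glycolysis 0.00. With the block and without saturated probes the respiratory chain test pointed to higher values than other genes. Spots of these 4 lists were often saturated. All 40 ribosomal protein genes were saturated on at least 1 array, so no fold is given for a member (list median -0.52, 38 lower adjusted over the list alone, camera adjusted p = 2.12e-22, and adjusted p = 0.282 with an estimated correlation). With saturated probes left out, an alternative chosen after seeing the data, glycolysis had an adjusted p of 0.112 against 1.74e-04 with them, the respiratory chain 0.898 against 0.0486 and histones 0.112 against 0.0162, all from camera, which called none of these 3. With an estimated correlation the camera adjusted p values of glycolysis, the respiratory chain and histones were 0.282, 0.690 and 0.460 with saturated probes in. Without saturated probes fry still called glycolysis lower (adjusted p = 0.0127, but 0.818 over 10 arrays without the block), and neither of the others (adjusted p = 0.935 and 0.406). It then also called the Notch list higher (adjusted p = 0.00732), which camera did not (adjusted p = 0.206), with medians of 0.03 in session 1 and -0.06 in session 2 over all members. Camera called the antigen presentation list only without saturated probes (adjusted p = 0.0346, and adjusted p = 0.275 with an estimated correlation), with HLA-DRA at 0.56 ± 0.12 and 4 members higher adjusted over the list alone. Its medians were -0.03 in session 1 and 0.13 in session 2 over all members.

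NF-kappaB and inflammatory mediators were not called as a list by camera (median -0.09 over 21 genes, adjusted p = 0.137) and were called lower by fry (adjusted p = 0.0128, and 0.00200 over 10 arrays without the block). The list medians were 0.03 in session 1 and -0.19 in session 2, so a lower median did not hold on the slide that carried both groups. IL32 and ICAM1 of this list fell and TRAF1 differed by -0.56 ± 0.16. In the interferon response list BST2 rose by 1.11 ± 0.19 (SE, adjusted p = 0.0388), ISG20 differed by -0.52 ± 0.12 and IFITM1 by 0.65 ± 0.15, and the list was not called by camera (adjusted p = 0.765). No list of markers of other cell types was called by camera or fry. The medians were -0.03 for 5 endothelial markers (adjusted p = 0.973), 0.00 for 13 blood cell markers (adjusted p = 0.966) and -0.09 for the 4 measured fibroblast markers, too few to test. The other lists without a call in this fit, by camera or by fry with saturated probes in, had medians of 0.00 for fatty acid oxidation, -0.05 for epithelial adhesion and keratins, 0.03 for intestinal differentiation, -0.05 for the cell cycle and 0.03 for p53 targets. They were -0.05 for endoplasmic reticulum chaperones, -0.13 for heat shock, -0.09 for lysosome and autophagy, -0.06 for receptor tyrosine kinases, 0.05 for MAPK feedback, 0.03 for Notch and 0.08 for semaphorins, plexins and ephrins, against -0.03 for all genes.

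**Figure D3:**
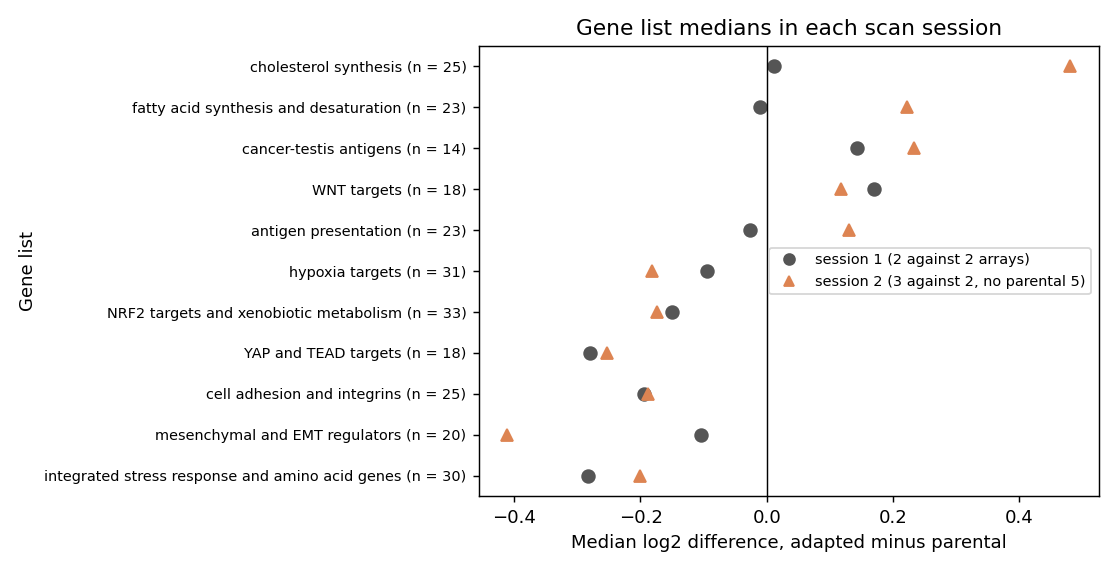
Median log2 difference (adapted minus parental) of the members of each gene list called by camera with saturated probes left out, on the horizontal axis, with circles for scan session 1 and triangles for session 2 without parental 5. The integrated stress response list lies at -0.28 in session 1 and -0.20 in session 2, while cholesterol synthesis lies at 0.01 in session 1 and 0.48 in session 2.

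In all, camera called 14 of 35 lists with the block and without parental 5, 11 of 34 with saturated probes left out, and none with an estimated correlation, where the lowest adjusted p was 0.15, or 0.0994 without saturated probes. Fry called 13, among them the angiogenic ligand and NF-kappaB lists, and did not call the fatty acid synthesis, respiratory chain and histone lists. Over all 10 arrays without the block camera called 6 of 35: cholesterol synthesis (adjusted p = 2.43e-07), fatty acid synthesis (0.00960), cancer-testis antigens (0.00960) and WNT targets (0.0441) higher, and mesenchymal (0.0206) and ribosomal protein genes (8.18e-19) lower, again none with an estimated correlation (lowest adjusted p = 0.196). With saturated probes left out, camera called 4 of 34 lists over the 10 arrays, and WNT targets lost their call (adjusted p = 0.0823). With saturated probes in, fry called 6 lists over the 10 arrays, all lower: mesenchymal (adjusted p = 0.0117), adhesion (0.00200), YAP and TEAD target (0.04), lysosome and autophagy (0.04), angiogenic ligand and NF-kappaB genes.

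The scan sessions served as separate comparisons of the same groups. Across 16227 genes, which are not independent replicates, the differences in session 1 and in session 2 without parental 5 had a Pearson r of 0.286 and a Spearman rho of 0.263, and 6 of 60 labelings of the arrays within sessions gave an r as high. Of the 100 genes with the lowest t in session 1, 87 were also lower in session 2, and of the 100 with the highest t, 51 were also higher. Of the 100 with the lowest and the 100 with the highest t in session 2, 78 were also lower and 77 also higher in session 1. Of all genes, 41.4% were higher in session 2 and 45.3% in session 1. No gene passed within session 1 alone, where limma had 2 arrays against 2 and 1101 genes had an unadjusted p under 0.05. In session 2 each group had a slide of its own, so slide and group cannot be told apart there.

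The authors' deposited table lists probes selected by a rank product comparison, 43 with a positive and 123 with a negative log2 fold change, of absolute size 0.502 to 1.69 and with an estimated false positive share of at most 0.0494. The column header in the authors' deposited table names a log2 fold change and gives no direction. For 161 of these probes the sign was that of adapted minus parental in both sessions computed here, and adapted over parental was taken as the direction. In the authors' deposited table IL32 stands at -1.69, TGFBI at -1.37, VIM at -1.26 and CEMIP at 1.25, all 4 among the 15 values that had lost their decimal sign and in which it was restored here. Of the 88 genes past the threshold with the block, 48 are among those of the authors' deposited table. Through the origin, the difference over 10 arrays had a slope of 1.44 on the authors' deposited value (Pearson r 0.934 across probes, which are not independent), so the deposited values were smaller than those computed here. The slope was 1.28 with the block and without parental 5, 1.16 in session 1 and 1.38 in session 2, or 1.66 there with parental 5. Values on a natural log scale would give 1.44, the slope over 10 arrays, but since the slope varied with the arrays used, the base of the deposited values was left open. That table was deposited with these same arrays and is not independent evidence.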

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

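The tests of weak-spot noise on parental 5, of saturated spots, and of parental 5 and the slides in the cholesterol synthesis list were chosen only after the result was seen, as was the fit with the scan session as a block. Parental 5 had a median correlation with the other arrays of 0.898, against 0.959 to 0.970 on the other parental arrays. The gap to the nearest array of the group took up most of the group's range. By the same measure the normalized log2 signal stood apart on parental 5 for ANXA10 at -6.42, CEMIP at -4.74, ODAM at -5.93 and CALB2 at -0.22. It did so on adapted 4 for ANXA10 at -3.31 and on adapted 1 for ODAM at -4.80. Chance marks about 1 in 20 groups, and this marked 1 of 14 groups of array measures and 6 of 48 groups of named gene values. The group difference of MYBPH differed between scan sessions by -3.05 ± 0.26 (SE, limma adjusted p = 0.0194), 1.57 in session 1 and -1.48 in session 2, without parental 5.

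Parental 5 stood apart from the other arrays, and 3 technical explanations were tested. Against noise in weak spots as the whole cause, its highest rank correlation with parental 3 or 4 over the brightest unsaturated probes was 0.875, and that between parental 3 and 4 was 0.960. Against probe GC content, its spread after removal of that trend was 3.31 times that of the next array. Against a mislabelled array of adapted cells, it lay at -0.0753 on a scale from the parental mean at 0 to the adapted mean at 1. A difference in RNA or hybridisation, or in the culture itself, may remain, and neither was tested.

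Ribosomal protein, glycolysis, histone and respiratory chain genes had lower normalized values in adapted cells with the block, but the respiratory chain did not with quantile normalization (0.02), nor it or glycolysis over 10 arrays without saturated probes (medians 0.08 and 0.00). Adapted arrays were brighter, by 0.52 at the 75th percentile, and genes saturated on all 9 arrays differed by -0.51, which subtraction of a higher percentile from a fixed ceiling could give. The ribosomal protein median lay -0.00594 from minus that gap. With saturated probes left out, the lowest adjusted p of camera or fry for the histone and respiratory chain lists was 0.112, so saturation may account for these and for the ribosomal protein list, and a change in the cells stays open. For glycolysis camera lost its call (0.112) while fry called the unsaturated members lower with the block (adjusted p = 0.0127) and not over 10 arrays (0.818), so whether saturation was the cause stays open.

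Cholesterol synthesis genes were higher as a list in adapted cells. Parental 5 was not the source of the call, since without it and with the block the camera adjusted p was 1.17e-08, although the call was lost with an estimated correlation there as over 10 arrays (adjusted p = 0.186 and 0.196). On slide 1, which holds both groups, the list median exceeded that of all genes by 0.0281, and in session 2 by 0.53, so a difference between the slides of session 2 may account for it. A median as far from that of all genes came from 2 of 60 splits within sessions (real value 0.348, highest other 0.368), and since the list was picked from 35 for its low p, chance is not excluded. An effect of adaptation on the session 2 arrays cannot be separated from those slides.

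As many genes as the 7 found over 10 arrays came from 4 of 100 splits, and the highest other had 4522. Of 5 splits drawn that put all 4 arrays of session 1 in a single group, 3 gave 4522, 3148 and 1978 genes and the other 2 gave 1 and 0. The count in these splits thus also varied with the session 2 array that joined session 1. The session itself had a wide effect: in limma with the group in the fit and without parental 5, 10329 of 18231 genes differed between sessions. With the session as a block 8 genes were higher and 14 lower. With the block and without parental 5, 2 of 60 splits within sessions gave as many as the real 88, and the highest other had 187. For gene lists, chance cannot be excluded over 10 arrays, where 13 of 100 splits gave as many as the real 6 (highest other 12). With the block 1 of 60 did (real 14, highest other 11). For the count of genes over 10 arrays, the 4 of 100 splits include the real one. The 3 others held all of session 1 in a single group, unlike the real split. Every other drawn split that divided session 1 between the groups gave 0 genes. The 4 of 100 therefore mixes the session with chance and is no clean measure of chance, which is not excluded there. With the block and that fit taken as given, few splits reached the real counts of genes and lists. Chance is not excluded, since the split counts do not correct for the choice of that fit after seeing the data. Across all genes 6 of 60 labelings gave a correlation between sessions as high as the real 0.286, so chance cannot be excluded there.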

How the results depend on the processing

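The scan session as a block, the replicate block, the omission of saturated probes and every alternative to the fit with the block and without parental 5 were chosen only after the result was seen. Of the named genes, 24 of 124 over 10 arrays and 19 of 125 with the block changed sign under at least 1 alternative, 14 of the latter in session 1 alone, CA9 and NRP1 among them. None of these passed the threshold with or without that alternative. The respiratory chain list, called lower with the block, had a median of 0.0195 with quantile normalization, and without saturated probes its median was -0.0215 while its test pointed to higher values than other genes (adjusted p = 0.898). The cell cycle list, not called over 10 arrays, was called lower with slide as a fixed block and on slide 1 alone, with a median of -0.11 in both. Both rest on the difference within slide 1 and are not separate results. Over 10 arrays, 2 and 5 genes were higher and lower, all at least 2-fold, and these counts, which were the same at 2-fold unless given, became 0 and 0 with normexp, 2 and 3 with quantile normalization, 1 and 3 without a filter on dim probes and 0 and 5 with a filter on all 10 arrays. They were 1 and 3 with the mean over probes, 1 and 3 with a trended and robust variance, 0 and 3 with slide as a fixed block and 2 and 7 with a random block. They were 0 and 0 on slide 1 alone, 0 and 0 on slides 2 and 3 alone and 0 and 0 at an adjusted p below 0.01. None of the 7 genes was among those called with slide as a fixed block. In that fit the group difference comes from slide 1 alone, since slides 2 and 3 hold 1 group each. With quantile normalization 1 higher and 2 lower of the 7 were called, and with the random block 2 and 4. Array weights gave 20 and 46 (13 and 32 at 2-fold) and 14 lists, the session block 8 and 14 (8 and 12 at 2-fold), and the block without parental 5 25 and 63 (15 and 24 at 2-fold) and 14 lists. A replicate block gave 0 and 2 over 10 arrays and 6 and 7 in place of the session block. Deviations from the group means of arrays with the same number had correlations of 0.351 to 0.775, but these arrays share a scan session. Within sessions the range was -0.188 to 0.483. In session 1 both numbers correlated best with their own partner (0.483), a single value, since 2 arrays per group mirror each other. In session 2 not every array did. The arrays were read as sharing only a number, but a pairing within session 1 stays open. Leaving out each array gave 0 to 5 higher, 0 to 7 lower, 0 to 5 and 0 to 7 at 2-fold, and 4 to 14 lists. Camera with an estimated correlation called 0 lists in both fits. From 25 and 63 with the block and without parental 5, the counts became 0 and 0 with normexp (lowest adjusted p 0.0519), 9 and 25 without a filter, 12 and 59 with the filter on all 10 arrays and 51 and 93 with array weights. They became 12 and 26 with slide as a block (9 lists), 5 and 7 without a block, 8 and 14 with parental 5 put back (7 lists). They became 0 and 0 in session 1 alone (8 lists), 42 and 96 in session 2 alone and 10 and 25 at an adjusted p below 0.01. Of the 88 genes, 7 higher and 14 lower were among those called with slide as a block. In session 2 alone 14 higher and 30 lower of the 88 were called. Leaving out each array gave 11 to 24 higher, 30 to 67 lower and 12 to 16 lists. Fewer arrays go by construction with the counts of 0 on slide 1 and in session 1, and a stricter threshold with those at 0.01. With slide as a fixed block, too, only the arrays of slide 1 inform the group difference. The number of arrays does not account for the counts on slides 2 and 3, where 6 arrays gave 0 and 0 and the 5 without parental 5 gave 42 and 96. Those fits differ in parental 5, so the counts of 0 went with its inclusion. Why that array had this effect was not tested, nor was the cause of the other changes in counts. Spots near background limit the calls on MSR1, DKK4, ODAM and GAGE12F to lower bounds. The authors' values per array, planned as an alternative, were not run because the deposited table holds none.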

Other observations

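The genes of this paragraph were named after their values were seen, and the test of chromosome regions was chosen only after the result was seen. With the session as a block and without parental 5, transcripts for the transglutaminase TGM2 (-0.95 ± 0.14, SE), the transcription factors RUNX1 (-0.84 ± 0.13) and KLF2 (-0.72 ± 0.12), the kinase CDK6 (-0.68 ± 0.12) and the collagen-modifying oxidase LOXL4 (-0.93 ± 0.13) were lower in adapted cells, with limma adjusted p from 0.0159 to 0.0467. ACVRL1, a receptor of the TGF-beta family, differed by -0.92 ± 0.16 (adjusted p = 0.0399). ISM1, a secreted protein, differed by 0.71 ± 0.10 (adjusted p = 0.0169). In the NRF2 list AKR1B10 differed by -0.54 ± 0.12 and in the list of epithelial genes KRT19 by -0.60 ± 0.14, neither past the threshold over all genes.

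Gain or loss of chromosome regions in adapted cells could shift neighbouring genes together. Over 442 windows of 40 neighbouring genes, the highest absolute median shared by both scan sessions was 0.123, 0 windows reached 0.3 in both sessions, and the window medians of the sessions had a correlation across windows of -0.00455. This argues against a gain or loss of that size carried by most adapted cells of both sessions.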
